A study of Mus musculus with 10 samples.

How the data were processed

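Droplet single-cell RNA libraries of the whole somatosensory cortex of C57BL/6JRj mouse embryos were used, 2 at each of E13, E15, E16, E17 and E18. Per the labels, meninges were removed, tissue was dissociated with papain and libraries were made with 10x Genomics v3 chemistry. The deposited values are raw UMI counts per gene and cell, 1 matrix per library, not pooled across libraries. The counts were made with Cell Ranger, named in the submitters' processing notes, and version 3.1.0 stands in the matrix header. The genome build was mm10 per the processing notes, and the annotation is not given in the sources used here. The barcodes had already been limited to called cells by the submitters. The chromatin accessibility, methylation with Hi-C and reporter assay data of the series were not analysed here.

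The 10 matrices held 61258 barcodes and 31053 genes, of which 35 symbols belonged to more than 1 identifier and were kept apart by identifier. Barcodes with fewer than 1000 detected genes (11579) or more than 10% mitochondrial UMIs (18920) were left out, and 38509 passed. Scrublet, as implemented in scanpy, was run on each library with an expected rate of 0.06. Where its automatic threshold marked less than 0.5% of a library, the median threshold of the other libraries was used instead. This applied to E13 replicate 2, where the automatic threshold marked 0.0945%, and the threshold became 0.245. In all 1008 cells (2.62%, from 0.756% to 4.52% per library) were taken out as predicted doublets and 37501 were kept. Free RNA in the droplets was not removed.

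Cells kept were normalized, 2000 variable genes were chosen, and 40 principal components and 15 neighbours went into Leiden clustering at resolution 1. Library or age was not corrected for. A marker counted as raised in a cluster when its level, with 20 CPM added to both sides, was at least 1.5 times the mean of the other clusters and at least 20% of cells held it. Each cluster took the type with the largest share of its markers raised. It stayed unnamed with fewer than 3 raised markers, when another type had more markers among its 10 top genes, or when its UMIs were low and no marker was among those genes. Names carry "-like" since they rest on transcripts alone. Marker lists were set for NSC, IPC, newborn, upper-layer and deep-layer excitatory neurons, Cajal-Retzius cells, interneurons, oligodendrocyte precursors, astrocytes, microglia, border macrophages, endothelial, mural, fibroblast, red blood, choroid plexus and ependymal cells.

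UMIs were summed over the cells of a class in each library, with at least 20 cells per sum, so that libraries and not cells are the replicates. Age trends were fitted with edgeR (quasi-likelihood F test, TMM, filterByExpr) on age as a number, in NSC-like and IPC-like cells over 10 libraries. The newborn neuron trend used the 8 libraries of E15 to E18, because too few E13 cells carried that name at resolution 1. Its changes are given over 3 days. For NSC-like cells, E18 against E13 and each pair of neighbouring ages were contrasts of 1 fit with age as a factor. IPC-like and NSC-like slopes were compared by their interaction with age, with library as a block. A gene was called at an adjusted p (Benjamini-Hochberg) under 0.05. Standard errors of log2 changes were taken from the change and its F statistic. Levels are CPM on TMM-scaled library sizes.

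Gene lists were tested with limma camera on voom values at an inter-gene correlation of 0.01, for lists with at least 3 members tested. They covered early cortical progenitor, astroglial, oligodendrocyte lineage, outer radial glia, Notch, Wnt beta-catenin, BMP and Id, FGF and ERK target, Hedgehog, S phase, G2/M, neurogenic differentiation, deep-layer and upper-layer identity genes. They also covered DNA methylation machinery, cohesin and CTCF, Polycomb, cholesterol synthesis, glycolysis and hypoxia, immediate early and dissociation, cytosolic ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes, beside the cell type markers. The ribosomal protein, oxidative phosphorylation and mitochondrially encoded lists were set by patterns of gene symbols, and the others were written by hand. Phase calls used the same S and G2/M lists, so list tests and phase shares are not separate results.

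Shares of cells per class were related to age by two-sided permutation tests of Pearson's r and Spearman's rho, with 100000 permutations over 10 libraries (smallest possible p 1e-05) and all orders of the ages over 8 libraries. The share of NSC-like cells called S or G2/M was scored with scanpy within the class after each cell was thinned to 2000 UMIs. The G1-only alternative used phase calls scored over all kept cells, a different scoring.

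Genes were named by a rule. For each trend these were the 10 largest positive and 10 largest negative slopes among called genes with a mean of at least 20 CPM over the ages and both E18 libraries beyond both E13 libraries (E15 for newborn neurons). Predicted genes, sex-linked genes, mitochondrial genes and markers of blood, vessel, immune, fibroblast and choroid plexus cells were left out of this ranking. Up to 4 members with the smallest p were named per list, and 5 genes in each direction for the interaction. Regulators set in advance were named whatever their result: Pax6, Sox2, Hes1, Hes5, Eomes, Neurog2, Hmga2, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Ctcf and Ezh2 in progenitors, and Bcl11b, Fezf2, Tbr1, Sox5, Cux1 and Pou3f2 in newborn neurons. Some genes that these rules select are not reported here. Coordinates came from GENCODE vM21, which held 30934 of the 31053 identifiers. These comparisons, tests, lists, naming rules and most alternatives were fixed before the data were examined. The 8-library newborn trend, the replacement Scrublet threshold, the looser mitochondrial limit, the E15 to E18 trends, the fits without E16 replicate 1 and E18 replicate 1, and the joined Olig1 and Olig2 cluster were chosen afterwards.

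Alternatives tried were DESeq2 size factors in edgeR, DESeq2 Wald tests, no filter on low counts, each library left out, a replicate term, predicted doublets kept, a stricter cell filter (at least 1500 genes and at most 5% mitochondrial UMIs), a looser one (at most 20%), sums thinned to the smallest total, Leiden resolution 2, G1 cells only, and cells holding Pax6 without Eomes, Neurod2 or Neurod6. Lists were also tested with estimated correlation and with fry, and phase shares unthinned and at 3000 UMIs.

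Depth fell with age. Median UMIs per barcode were 14143 and 14411 at E13, 15019 and 13751.5 at E15, 8561 and 9720.5 at E16, 7480.5 and 6933 at E17, and 5149 and 5323 at E18. Kept cells numbered 4259 and 4084, 3589 and 3514, 2555 and 4071, 4025 and 4645, and 1838 and 4921 in the same order. A level that corresponds to 3 UMIs was 0.623 CPM in the smallest NSC-like sum. The fits were tested on simulated data with these library sizes, in which 200 genes changed, of 12036 tested in the NSC-like trend. Counts were drawn independently for each gene, so the rates below may not hold where many genes change together. In the NSC-like trend edgeR recovered 11.9%, 59.7% and 95.5% of genes that changed by log2 0.5, 1 and 2, and 8 of 119 calls were false (6.72%). In the IPC-like trend it recovered 10.4%, 68.7% and 92.4%, and in the newborn trend 11.9%, 56.7% and 90.9%, with 2 of 116 and 3 of 109 calls false. For E18 against E13 it recovered 7.46%, 61.2% and 87.9%, with 10 of 114 calls false, and for the interaction 13.4%, 76.1% and 86.4%.

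Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.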

Results

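Cells of the whole somatosensory cortex of C57BL/6JRj mouse embryos were profiled by droplet single-cell RNA sequencing (10x Genomics, v3 chemistry) at 5 ages, E13, E15, E16, E17 and E18. Each age had 2 libraries, 10 in all. Total UMIs per library were 89093339 and 77071990 at E13, 78716453 and 62708554 at E15, 63667351 and 62164328 at E16, 46659713 and 52513768 at E17, and 42001087 and 58004986 at E18. Median UMIs per barcode went from 14143 and 14411 at E13 to 5149 and 5323 at E18. After filtering and doublet removal 37501 of 61258 barcodes were kept, between 1838 cells in E18 replicate 1 and 4921 in E18 replicate 2. Clusters were named from marker genes as neural stem cell-like (NSC-like), intermediate progenitor-like (IPC-like), newborn excitatory neuron-like and other classes, and UMIs were summed per library within a class. The NSC-like sums held between 4814108 UMIs (E18 replicate 1) and 34614308 UMIs (E13 replicate 2). A count of 3 UMIs equals 0.623 CPM in the smallest of these sums and 0.112 CPM in that of E13 replicate 1. The labels do not say whether the libraries of an age came from separate animals. P-values of the gene, share and phase tests therefore measure the spread between these libraries. Those of the list tests by camera compare the genes of a list with the other genes, at a set correlation. All tests were two-sided, gene tests were edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment, and levels are CPM with SD, n = 2 libraries per age.

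The first comparison asked which transcripts of NSC-like cells change steadily over the neurogenic period. Sparcl1, which encodes a secreted matrix glycoprotein of astroglia, went from 1.12 ± 0.484 CPM at E13 to 306 ± 11.2 at E18, a fitted log2 change over 5 days of 8.14 ± 0.24 (SE, adjusted p = 2.04e-11). Tnc, the gene of the extracellular matrix protein tenascin C, went from 2.39 ± 1.62 to 637 ± 28.7 CPM (log2 7.67 ± 0.83, adjusted p = 3.93e-06). Aldh1l1, a folate enzyme gene widely used to mark astrocytes, went from 0.947 ± 0.632 to 206 ± 48.7 CPM (log2 7.65 ± 0.43, adjusted p = 6.38e-09), and Luzp2 from 0.96 ± 0.144 to 271 ± 44.3 CPM (log2 8.73 ± 0.35). Slco1c1, a thyroid hormone transporter gene, stood at 0.105 CPM at E13, about the level of 3 UMIs, and reached 299 ± 2.01 CPM at E18. Baalc, Slc6a11, Cybrd1 and S100a16 rose from under 1 CPM to 87.9, 79.6, 60.5 and 90.9 CPM. Ifitm3 completed the 10 largest rises with 82.1 ± 78.9 CPM at E18, a level that differed widely between its libraries.

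The largest single-gene falls in NSC-like cells were picked by slope. Hmga2, a chromatin architecture factor of young stem cells, dropped from 107 ± 28 to 2.84 ± 1.07 CPM (log2 -4.37 ± 0.37, adjusted p = 4.01e-07). The RNA-binding protein genes Igf2bp2 and Igf2bp1 fell by 2.83 ± 0.2 and 2.6 ± 0.19 on the log2 scale, with Igf2bp1 going from 152 ± 5.22 to 21.4 ± 2.65 CPM (adjusted p = 8.49e-08). Jph1 (log2 -3.29), the nuclear receptor gene Nr4a2 (log2 -3.26), Shisa2 (log2 -3), the protocadherin gene Pcdh19 (log2 -2.9), Flrt3 (log2 -2.85), Gpc1 (log2 -2.59) and Snhg12 (log2 -2.55) made up the rest of the 10 largest falls, each with both E18 libraries below both E13 libraries.

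In all, 3155 genes rose and 2999 fell with age in NSC-like cells among 12298 tested. On the genome (mm10), 4 of the changed genes lie as follows: Sparcl1 (ENSMUSG00000029309, protein coding, chromosome 5, 104079111 to 104113733, minus strand), Tnc (ENSMUSG00000028364, protein coding, chromosome 4, 63959785 to 64047015, minus strand), Hmga2 (ENSMUSG00000056758, protein coding, chromosome 10, 120361275 to 120476469, minus strand) and Igf2bp1 (ENSMUSG00000013415, protein coding, chromosome 11, 95957163 to 96005940, minus strand). NSC-like cells at E13 came from clusters 6 and 12 and at later ages from clusters 10, 13 and 16. The finer clustering held an NSC-like cluster of 666 cells with 8 of 10 astrocyte markers raised and Tnc, Slco1c1 and Aldh1l1 among its top genes. It had no cells at E13 or E15, 12 and 18 at E16, 119 and 125 at E17, and 127 and 265 of the 264 and 489 NSC-like cells of that clustering at E18. The largest rises were not tested without this subset. In cells called G1 alone 1878 genes rose and 1478 fell among 9572 tested, and in cells taken by Pax6 without neuronal or IPC genes 2119 rose and 1863 fell among 10978 tested.

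Among the regulators named in advance, the stem cell transcription factor Pax6 fell slightly in NSC-like cells (log2 -0.43 ± 0.16 over 5 days, adjusted p = 0.0321), from 417 ± 11.4 to 322 ± 14.8 CPM. That call lay near the threshold: the slope of -0.086 log2 per day became -0.078 without E17 replicate 1, -0.085 without E17 replicate 2, -0.085 without E18 replicate 1 and -0.075 without E18 replicate 2, none past the threshold. Sox2 did not pass (425 ± 36.7 to 390 ± 71.3 CPM, adjusted p = 0.307), but passed at -0.071 log2 per day without E18 replicate 1 and at -0.07 with replicates 1 of both E16 and E18 left out. The Notch effector Hes1 fell by 1.6 ± 0.36 on the log2 scale (adjusted p = 0.00187), from 455 ± 24.3 CPM at E13 and 626 ± 101 at E15 to 168 ± 5.84 at E18. Hes5 did not follow a line with age (adjusted p = 0.264): it stood at 813 ± 248 CPM at E13, 1900 ± 17 at E15 and 1210 ± 56.2 at E18, and over E15 to E18 alone its slope passed at -0.22 log2 per day. Neurog2, which drives neurogenesis, fell by 1.92 ± 0.24 (adjusted p = 1.61e-05), from 232 ± 44 to 74.1 ± 19.7 CPM. Eomes, the marker of intermediate progenitors, rose by 0.91 ± 0.2 on the log2 scale in NSC-like cells (36.8 ± 6.47 to 68.3 ± 8.2 CPM, adjusted p = 0.00154). The Eomes slope of 0.18 log2 per day was not past the threshold at 0.018 with the stricter cell filter, 0.056 in G1 cells, 0.087 with predicted doublets kept, 0.067 with the Olig1 and Olig2 cluster joined, and 0.1 from E15 to E18 alone.

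Chromatin regulators named in advance went both ways in NSC-like cells. The Polycomb methyltransferase gene Ezh2 fell by 0.85 ± 0.2 on the log2 scale (397 ± 1.78 to 196 ± 3.6 CPM, adjusted p = 0.00288). The DNA methyltransferase gene Dnmt3b fell by 1.74 ± 0.31 from a low level (6.86 ± 0.193 to 1.99 ± 0.671 CPM, adjusted p = 0.000334). Dnmt1 (adjusted p = 0.409), Dnmt3a (adjusted p = 0.995) and the loop-anchoring factor Ctcf (adjusted p = 0.212) did not pass. Tet1 rose by 0.49 ± 0.17 (29.1 ± 8.13 to 40.8 ± 4.2 CPM, adjusted p = 0.0281). Its slope of 0.098 log2 per day was not past the threshold at 0.059 without E13 replicate 2, 0.086 without E18 replicate 2, 0.082 with no filter on low counts, 0.097 in G1 cells, 0.093 with the Pax6 gate and 0.025 with the Olig1 and Olig2 cluster joined.

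**Figure D1:**
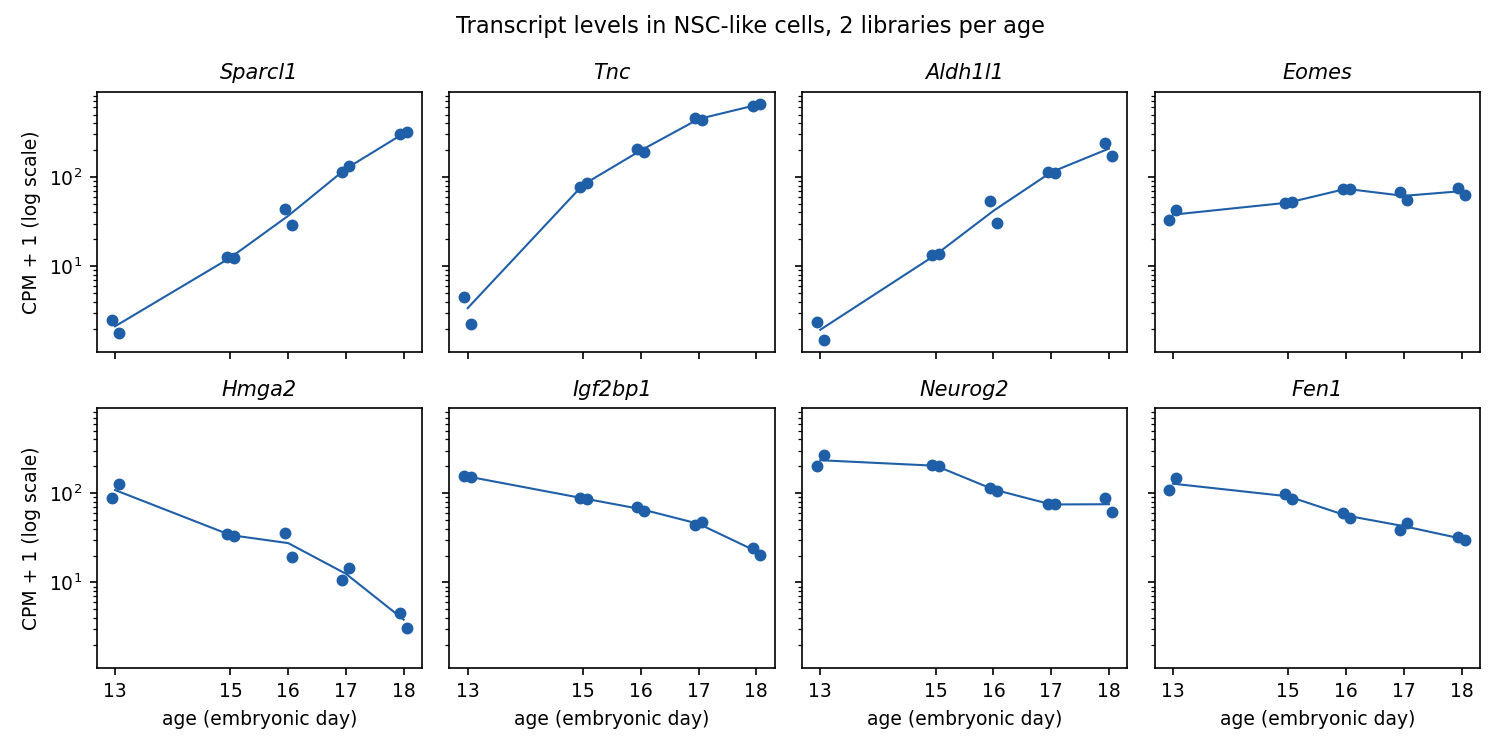
Levels of 8 genes in NSC-like cells against age in embryonic days, as CPM + 1 on a log scale. Each point is 1 of 2 libraries per age and each line joins the means; Sparcl1 goes from 1.12 to 306 CPM between E13 and E18 and Hmga2 from 107 to 2.84 CPM.

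The end points were also compared directly. Between E13 and E18 NSC-like Tnc rose by 8.06 ± 0.36 on the log2 scale (SE), Luzp2 by 8.11 ± 0.22 (adjusted p = 2.05e-10) and Sparcl1 by 8.08 ± 0.27, while Hmga2 fell by 5.25 ± 0.36 (adjusted p = 2.3e-07) and Igf2bp1 fell by 2.84 ± 0.14. Neurog2 fell by 1.66 ± 0.18 and Hes1 fell by 1.45 ± 0.16 (adjusted p = 1.21e-05), and Hes5 did not pass (log2 0.56 ± 0.23, adjusted p = 0.0571). Of 12658 genes tested, 3441 were higher and 3151 lower at E18 than at E13. In G1 cells alone the counts were 1876 and 1506, and with the Pax6 gate 2165 and 1661.

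Changes in NSC-like cells were then placed between neighbouring ages. From E13 to E15 Tnc rose by 5.09 ± 0.32 (log2, SE), Sparcl1 by 3.37 ± 0.27 (adjusted p = 1.09e-05), Aldh1l1 by 3.74 ± 0.38 and the proteoglycan-type phosphatase gene Ptprz1 by 1.61 ± 0.21. Hes5 rose by 1.22 ± 0.23 (adjusted p = 0.00664). Over the same step Hmga2 fell by 1.7 ± 0.25, Flrt3 fell by 1.66 ± 0.18 and Nr4a2 fell by 1.36 ± 0.21. From E15 to E16 Hes1 fell by 0.96 ± 0.16 (adjusted p = 0.0141), Neurog2 fell by 0.88 ± 0.18 and Id4, which encodes an inhibitor of basic helix-loop-helix factors, fell by 0.8 ± 0.15, while Luzp2 rose by 1.97 ± 0.2. From E16 to E17 the immediate early gene Egr1 rose by 2.28 ± 0.23 (adjusted p = 0.000385), Luzp2 by 2.41 ± 0.17 and Fgfbp3 by 1.04 ± 0.16. From E17 to E18 Gfap, the glial intermediate filament gene, rose by 2.37 ± 0.34 (adjusted p = 0.00421) to 31.7 ± 14.1 CPM, and Hmga2 and Igf2bp1 fell by 2.03 ± 0.44 and 1.06 ± 0.14.

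The number of genes past the threshold at each step of NSC-like cells depended on single libraries. Between E13 and E15, 558 genes were higher and 324 lower, 882 in all. That total was 304 without E15 replicate 1 and 313 without E15 replicate 2. Between E15 and E16, 76 were higher and 64 lower, 140 in all. Left out in turn, E13 replicates 1 and 2 gave 329 and 321, E15 replicates 1 and 2 gave 5 and 18, E16 replicates 1 and 2 gave 17 and 65, and E17 replicates 1 and 2 gave 65 and 70. Between E16 and E17, 110 were higher and 18 lower, 128 in all. Here E13 replicates 1 and 2 gave 224 and 234 when left out, E15 replicates 1 and 2 gave 83 and 82, E16 replicates 1 and 2 gave 62 and 62, and E17 replicates 1 and 2 gave 34 and 30. Between E17 and E18, 409 were higher and 206 lower, 615 in all. Without E17 replicate 1 edgeR called 0 genes at this step, with 1661 at an unadjusted p under 0.05, and DESeq2, run on all libraries alone, called 666. The total was 24 without E17 replicate 2, 124 without E18 replicate 1, 352 without E18 replicate 2, and 249 and 259 without E15 replicates 1 and 2.

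Gene lists fixed in advance were tested in NSC-like cells with limma's camera at a set correlation. Of 34 lists with enough genes, 17 passed, and 3 of these (astroglial, outer radial glia and the astrocyte markers) passed with an estimated correlation as well. These 3 lists share members and are not separate results. Most astrocyte markers are also in the astroglial list, and Tnc and Ptprz1 are in both the astroglial and outer radial glia lists. In the astroglial list 24 of 30 genes rose and 2 fell (24 and 2 adjusted over the list alone), with a median log2 change of 3.07 (adjusted p = 6.11e-12, adjusted p = 0.0405 with an estimated correlation). Sparcl1 and Ptprz1 (133 ± 45.1 to 2220 ± 318 CPM) were among its members with the smallest p-values. All 8 outer radial glia genes rose (8 adjusted over the list alone, adjusted p = 3.79e-06), with Itgb5 from 1.05 ± 0.0298 to 62.2 ± 10.9 CPM, Acsbg1 from 11.5 ± 0.883 to 103 ± 19.9 CPM and Pea15a from 286 ± 59.5 to 991 ± 153 CPM. All 5 tested oligodendrocyte lineage genes rose (5 adjusted over the list alone, adjusted p = 0.00219), and adjusted p = 0.0735 with an estimated correlation. Olig2 stood at 16.2 ± 1.76 CPM at E18, Egfr at 20.7 ± 0.161 and Olig1 at 23 ± 3.11, with Olig1 and Egfr at or near the level of 3 UMIs at E13.

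Proliferation and early identity genes fell together in NSC-like cells. Of 42 S phase genes 39 fell and 0 rose by edgeR (41 and 0 adjusted over the list alone), with a median log2 change of -1.04 (adjusted p = 6.03e-13, adjusted p = 0.239 with an estimated correlation). The flap endonuclease gene Fen1 fell by 2.14 ± 0.17, Cdc6 by 2.11 ± 0.19 and Chaf1b by 1.46 ± 0.14. Rpa2 fell by 1.31 ± 0.12 but was on the rising side in G1 cells alone (slope 0.08 log2 per day). It is a member of the S phase list that sets the G1 calls. Of 52 G2/M genes 28 fell and 1 rose (28 and 1 adjusted over the list alone, adjusted p = 4.61e-06, adjusted p = 0.574 with an estimated correlation), among them Aurka (log2 -1.43 ± 0.19) and Psrc1 (log2 -1.14 ± 0.21). Of 13 early cortical progenitor genes 10 fell and 0 rose (10 and 0 adjusted over the list alone, adjusted p = 6.57e-06, adjusted p = 0.16 with an estimated correlation). Igf2bp3 fell by 1.84 ± 0.12, and Crabp2, a retinoic acid-binding protein gene, went from 43.8 ± 31.7 CPM at E13 to 0.378 CPM at E18, below the level of 3 UMIs. Of 23 Polycomb genes 14 fell and 2 rose (15 and 2 adjusted over the list alone, adjusted p = 0.000964, adjusted p = 0.295 with an estimated correlation), with Mtf2 (log2 -1.45 ± 0.11), Phc2 (log2 -1.33 ± 0.14) and Eed (log2 -1.27 ± 0.14) at the front. Of 15 DNA methylation genes 7 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0135, adjusted p = 0.133 with an estimated correlation), led by Gadd45a and by Uhrf1, the partner of maintenance methylation (119 ± 7.22 to 48 ± 10.6 CPM). That list did not pass over E15 to E18 alone (adjusted p = 0.0844).

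Metabolic and signalling lists of NSC-like cells split. Of 22 cholesterol synthesis genes 16 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 0.00038, adjusted p = 0.239 with an estimated correlation), with Hmgcs1 from 246 ± 72.8 to 662 ± 39.9 CPM. Of 20 glycolysis and hypoxia genes 13 fell and 3 rose (13 and 4 adjusted over the list alone), among them Pkm (1290 ± 145 to 446 ± 95.7 CPM) and Ldha (754 ± 97 to 351 ± 48.7 CPM), whereas the prolyl hydroxylase gene Egln3 rose by 2.78 ± 0.2. The glycolysis test lay at the threshold (adjusted p = 0.04995, adjusted p = 0.679 with an estimated correlation) and gave adjusted p = 0.953 over E15 to E18 alone. Of 14 FGF and ERK targets 9 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.00826, adjusted p = 0.239 with an estimated correlation), led by Spry2 (7.88 ± 1.18 to 88.7 ± 11.9 CPM) and Fgfbp3 (96.2 ± 19 to 576 ± 31.8 CPM). The receptor gene Fgfr3 fell by 1.14 ± 0.16. Of 80 cytosolic ribosomal protein genes 14 fell and 0 rose by edgeR (4 and 0 adjusted over the list alone), with a median log2 change of -0.37 (adjusted p = 0.00012, adjusted p = 0.687 with an estimated correlation). Upper-layer neuron identity genes were on the rising side, 13 of 20 against 2 falling (13 and 2 adjusted over the list alone, adjusted p = 0.00755, adjusted p = 0.239 with an estimated correlation). Among them Mef2c went from 11.6 ± 1.73 to 123 ± 34.3 CPM and Rorb from 15.9 ± 2.69 to 67.7 ± 11.1 CPM. Upper-layer neuron-like cells went from 0.0117% of kept cells at E13 to 18.9% at E18. The part of free RNA in this rise was not tested.

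Other lists did not pass in NSC-like cells. The Notch pathway had 2 genes rising and 4 falling of 20 (adjusted p = 0.846), with Dll1 (log2 -1.61 ± 0.16) and Hey1 (log2 -1.58 ± 0.2) falling and Jag1 (log2 1.84 ± 0.26) rising. The Dll1 slope of -0.322 log2 per day was not past the threshold at -0.107 with the Pax6 gate and -0.0198 with the Olig1 and Olig2 cluster joined. The Wnt pathway had 5 and 7 of 20 (adjusted p = 0.488), the BMP and Id genes 7 and 3 of 13 (adjusted p = 0.3), the Hedgehog pathway 3 and 3 of 10 (adjusted p = 0.846). Neurogenic differentiation had 5 and 7 of 17 (adjusted p = 0.566), deep-layer neuron identity 5 and 7 of 15 (adjusted p = 0.563) and cohesin with Ctcf 0 and 2 of 14 (adjusted p = 0.323; 0 and 0 adjusted over the list alone). Immediate early and dissociation genes had 6 rising and 6 falling of 18 (adjusted p = 0.759), with Fos from 21.6 ± 15 to 438 ± 63.7 CPM and Egr1 from 5.1 ± 0.0311 to 140 ± 18 CPM but Ier2 from 158 ± 11.9 to 64.6 ± 10.1 CPM. With the Olig1 and Olig2 cluster joined the Ier2 slope was -0.0941 log2 per day, not past the threshold. Oxidative phosphorylation had 10 and 4 of 82 (adjusted p = 0.207) and the mitochondrially encoded genes 0 and 0 of 13 by edgeR (adjusted p = 0.488). Id4 fell from 1450 ± 117 to 416 ± 34.9 CPM against the balance of its list. The median, mean and test differed in sign for the Notch, Wnt, Hedgehog, deep-layer identity and immediate early lists, and for the deep-layer and red blood cell marker lists.

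Marker lists of other cell types moved within NSC-like cells too. Astrocyte markers rose for 8 of 9 genes (8 adjusted over the list alone, adjusted p = 6.57e-06, adjusted p = 0.0405 with an estimated correlation). Interneuron markers rose for 8 of 10 with 1 falling (8 and 1 adjusted over the list alone, adjusted p = 0.00916, adjusted p = 0.402 with an estimated correlation). Summed over the list, interneuron markers did not rise, with 245 ± 24.2 CPM at E13 and 179 ± 25.6 at E18. Upper-layer neuron markers rose for 9 of 11 (9 adjusted over the list alone, adjusted p = 0.00196, adjusted p = 0.239 with an estimated correlation) and mural markers for 2 of 3 (2 adjusted over the list alone, adjusted p = 0.0135, adjusted p = 0.239 with an estimated correlation). The part of free RNA in the upper-layer and mural rises was not tested. Markers of NSC (4 rising, 3 falling of 12, adjusted p = 0.223), IPC (2 and 6 of 10, adjusted p = 0.082), newborn neurons (5 and 1 of 7, adjusted p = 0.082) and deep-layer neurons (4 and 7 of 13, adjusted p = 0.364) did not pass. The summed level of the NSC markers still rose, from 7780 ± 1400 CPM at E13 to 31800 ± 5270 at E18. Over E15 to E18 alone the IPC markers passed on the falling side (adjusted p = 0.0316) and the newborn neuron markers on the rising side (adjusted p = 0.0135). Over all ages the markers of Cajal-Retzius cells (1 and 0 of 3, adjusted p = 0.45), fibroblasts (2 and 0 of 3, adjusted p = 0.0584) and red blood cells (0 and 0 of 4 by edgeR, adjusted p = 0.846) did not pass either. Oligodendrocyte precursor, microglia, endothelial, choroid plexus and ependymal markers had fewer than 3 tested genes and were not tested as lists, and no border macrophage marker was tested. Haemoglobin and other red blood cell transcripts summed to 402 ± 540 CPM at E13, 8.41 ± 1.83 at E15 and 812 ± 1090 at E18.

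**Figure D2:**
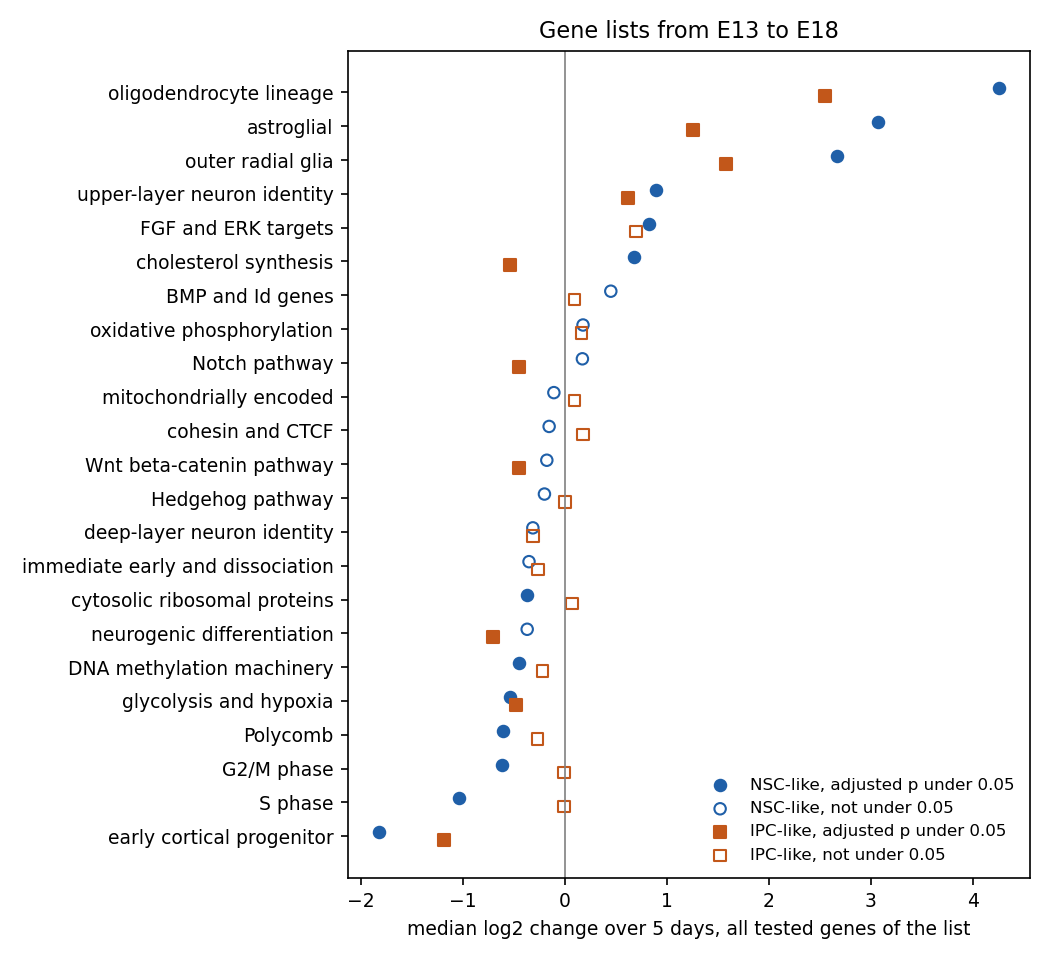
Median log2 change over 5 days of each gene list in NSC-like cells (circles) and IPC-like cells (squares), from sums of 10 libraries; filled symbols have a camera adjusted p under 0.05. S phase genes stand at -1.04 in NSC-like cells and -0.0089 in IPC-like cells.

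The same question was asked of IPC-like cells, the progenitors between stem cells and neurons. Dlgap1, a postsynaptic scaffold gene, rose in them from 1.81 ± 0.254 to 72.4 ± 5.58 CPM (log2 5.35 ± 0.24, adjusted p = 8.42e-10), and Egr1 from 2.39 ± 1.03 to 354 ± 96 CPM (log2 7.3 ± 0.54, adjusted p = 1.12e-07). Fos rose from 10.6 ± 6.22 to 134 ± 16.4 CPM. Cacng5, Abca1, Loxl1, Ptprz1, Chl1, Nav2 and Mef2c made up the rest of the 10 largest rises, with log2 changes from 3.48 to 5.33. Among the largest falls were Neurog1 from 99.3 ± 7.56 to 3.89 ± 1.33 CPM (log2 -4.25 ± 0.34, adjusted p = 2.93e-07), Dll1 from 222 ± 3.72 to 23.1 ± 1.53 CPM (log2 -3.41 ± 0.14, adjusted p = 8.42e-10) and Hey1 from 81.4 ± 11.4 to 5.95 ± 1.17 CPM. The cell cycle inhibitor gene Cdkn1c fell from 499 ± 144 to 49 ± 9.64 CPM, Gadd45g from 1810 ± 440 to 227 ± 118 CPM and Bcl11b, a deep-layer factor gene, from 194 ± 12.2 to 26.9 ± 4.22 CPM. The non-coding RNA gene Rmst fell by 4.5 ± 0.52, and Igf2bp2, Fzd1 and Nhlh1 completed the 10 largest falls. Neurog1 (ENSMUSG00000048904) lies on chromosome 13, 56250478 to 56252163, minus strand, and Dlgap1 (ENSMUSG00000003279) on chromosome 17, 69969073 to 70821413, plus strand (both protein coding).

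Eomes did not pass in IPC-like cells (759 ± 65.3 CPM at E13, 863 ± 63.8 at E18, adjusted p = 0.587). Alternatives called it in opposite directions. It passed as a rise in G1 cells alone with a slope of 0.12 log2 per day. With the stricter cell filter it passed as a fall with a slope of -0.0902 (adjusted p = 0.0341). Sox2 rose by 0.71 ± 0.12 on the log2 scale (119 ± 6.09 to 195 ± 3.21 CPM, adjusted p = 0.000368) but not past the threshold at the finer clustering (slope 0.06 log2 per day). Neurog2 fell by 0.83 ± 0.2 (adjusted p = 0.00467), and its slope of -0.17 log2 per day was not past the threshold at -0.088 in G1 cells and -0.17 over E15 to E18 alone. Hmga2 fell from 11.4 ± 5.56 CPM to 0.298 at E18, below the 0.942 and 0.883 CPM that 3 UMIs equal there. Pax6 rose by 0.51 ± 0.15 (201 ± 2.34 to 315 ± 27 CPM, adjusted p = 0.0157). Its slope of 0.1 log2 per day was not past the threshold at 0.0953 without E13 replicate 1, 0.0975 without E13 replicate 2, 0.0845 without E18 replicate 2, 0.055 at the finer clustering and 0.073 over E15 to E18 alone. Hes1, Hes5, Dnmt3a, Dnmt3b and Ctcf did not pass (adjusted p from 0.153 to 0.751). The Hes1 slope, -0.187 log2 per day, passed at -0.761 over E15 to E18 alone (adjusted p = 0.00541) and at -0.361 in G1 cells (adjusted p = 0.00297), and Ctcf passed at 0.0987 with the stricter cell filter. Dnmt1 rose by 0.86 ± 0.25 (adjusted p = 0.0152) and Tet1 by 0.58 ± 0.16 (adjusted p = 0.0131), the latter not past the threshold at 0.078 log2 per day without E13 replicate 2, 0.086 with the stricter cell filter and 0.1 over E15 to E18 alone. Dnmt1 was not past it at 0.1 log2 per day at the finer clustering and 0.23 over E15 to E18 alone. Ezh2 fell by 0.47 ± 0.15 (adjusted p = 0.0262), with slopes of -0.092, -0.07 and -0.081 log2 per day, none past the threshold, without E13 replicate 2, E18 replicate 1 and E18 replicate 2. It was not past the threshold either at -0.0745 with replicates 1 of both E16 and E18 left out, -0.045 with the stricter cell filter and -0.11 over E15 to E18 alone. Among 11878 genes tested 1886 rose and 1801 fell. Over E15 to E18 alone 872 rose and 566 fell, and with the stricter cell filter 1257 rose. IPC-like cells at E13 came mostly from cluster 11 and later from cluster 5, with clusters 15 and 17 at every age.

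Of 33 lists tested in IPC-like cells 14 passed, none of them with an estimated correlation. Interneuron markers rose for 10 of 12 genes (10 adjusted over the list alone, adjusted p = 7.58e-05, adjusted p = 0.137 with an estimated correlation). Neurogenic differentiation genes fell for 11 of 20 with 1 rising (13 and 1 adjusted over the list alone, adjusted p = 0.000147, adjusted p = 0.176 with an estimated correlation), among them Nhlh2 (60 ± 26.8 to 1.19 ± 0.0191 CPM) and Neurod1 (237 ± 12.7 to 100 ± 5.99 CPM). Astroglial transcripts in the IPC-like sums rose for 18 of 28 genes with 4 falling (18 and 5 adjusted over the list alone, adjusted p = 0.00025, adjusted p = 0.137 with an estimated correlation): Slc1a3 and Apoe reached 121 ± 13.1 and 64.1 ± 14.3 CPM, while the gap junction gene Gja1 fell by 3.19 ± 0.21. The part of free RNA in this rise was not tested, with astrocyte markers at 120 ± 0.313 CPM in IPC-like and 1150 ± 124 CPM in NSC-like cells at E18. Cholesterol synthesis genes fell for 11 of 22 with 0 rising by edgeR (11 and 0 adjusted over the list alone, adjusted p = 0.000562, adjusted p = 0.408 with an estimated correlation), led by Insig1 (log2 -1.02 ± 0.15). They turned to the rising side over E15 to E18 alone (adjusted p = 0.859). Notch pathway genes fell for 8 of 19 with 2 rising (9 and 2 adjusted over the list alone, adjusted p = 0.00871, adjusted p = 0.137 with an estimated correlation). Wnt pathway genes fell for 7 of 17 with 2 rising (7 and 4 adjusted over the list alone, adjusted p = 0.0122, adjusted p = 0.27 with an estimated correlation).

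Lists tied to timing moved in the sums of IPC-like cells in the direction seen in NSC-like cells. Free RNA was not removed, and its part in the rises below was not tested. Early cortical progenitor genes fell for 7 of 13 with 1 rising (7 and 1 adjusted over the list alone, adjusted p = 0.000562, adjusted p = 0.176 with an estimated correlation), with Igf2bp1 at log2 -2.33 ± 0.14. Outer radial glia genes rose for 6 of 7 (6 adjusted over the list alone, adjusted p = 0.000562, adjusted p = 0.142 with an estimated correlation). Upper-layer identity genes rose for 12 of 19 with 1 falling (12 and 1 adjusted over the list alone, adjusted p = 0.000757, adjusted p = 0.176 with an estimated correlation), with Pou3f2 from 202 ± 47.2 to 785 ± 52.2 CPM. Oligodendrocyte lineage genes rose for 2 of 4 (3 adjusted over the list alone, adjusted p = 0.0385, adjusted p = 0.176 with an estimated correlation). Glycolysis genes fell for 12 of 20 with 3 rising (13 and 3 adjusted over the list alone, adjusted p = 0.00248, adjusted p = 0.408 with an estimated correlation), though not over E15 to E18 alone (adjusted p = 0.501). Markers of IPC fell (6 of 10, 8 adjusted over the list alone, adjusted p = 0.000562, adjusted p = 0.27 with an estimated correlation). Markers of upper-layer neurons and astrocytes rose (7 of 10 and 5 of 6, adjusted p = 0.00161 and 0.00266; adjusted p = 0.163 and 0.137 with an estimated correlation). S phase genes did not pass (0 rising by edgeR and 3 falling of 42, adjusted p = 0.678), nor did G2/M genes over all ages (5 and 3 of 52, adjusted p = 0.746). G2/M genes were on the rising side over E15 to E18 alone (adjusted p = 1.52e-06). The Hedgehog and Polycomb lists passed on the falling side over E15 to E18 alone (adjusted p = 0.00433 and 0.0388). So did the ribosomal protein list (adjusted p = 0.000624), while immediate early genes passed on the rising side (adjusted p = 0.0185). The median, mean and test differed in sign for the BMP and Id, Hedgehog, deep-layer identity, immediate early and G2/M lists.

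At resolution 1 only 4 E13 cells were named newborn excitatory neuron-like, against 1033 and 648 per library at the finer clustering. Newborn excitatory neuron-like cells of resolution 1 were therefore compared over E15 to E18. Grin2b, an NMDA receptor subunit gene, rose in them from 6.87 ± 0.0942 to 72.3 ± 17.4 CPM (log2 over 3 days 3.24 ± 0.26, adjusted p = 6.21e-06). The axon guidance receptor gene Robo1 rose from 16.3 ± 1.65 to 86.2 ± 10.9 CPM and Mef2c from 31.9 ± 2.21 to 185 ± 42.3 CPM. Zbtb20 rose from 259 ± 3.86 to 1100 ± 83.2 CPM, and Chd5, Prkar1b, Pbx3 and Fam19a2 were also among the 10 largest rises (log2 from 2.02 to 2.76). Cck reached 66.6 ± 77.3 CPM and Opcml 94.3 ± 57.3 CPM at E18. Their slopes were 0.8 and 0.61 log2 per day, not past the threshold, without E18 replicate 2. Among the largest falls were Nhlh1 from 63.8 ± 2.6 to 9.2 ± 4.49 CPM (log2 -3.09 ± 0.28, adjusted p = 1.57e-05), Nhlh2 from 66.2 ± 3.95 to 11.4 ± 1.9 CPM, Dll1 from 39.5 ± 12 to 8.87 ± 0.761 CPM and Gadd45g from 238 ± 53.8 to 29.5 ± 0.286 CPM. Dusp14, Tuba4a, Sema6d, Slc17a7 and Shisa2 fell by 1.91 to 2.6 on the log2 scale.

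Layer genes named in advance were followed in newborn neuron-like cells. The deep-layer factor genes Fezf2 (107 ± 5.07 to 29 ± 6.07 CPM, log2 -2.01 ± 0.19, adjusted p = 1.77e-05), Bcl11b (306 ± 0.0975 to 113 ± 0.671 CPM, log2 -1.48 ± 0.13) and Sox5 (288 ± 1.07 to 135 ± 5.77 CPM, log2 -1.11 ± 0.12) fell. The deep-layer identity list as a whole did not pass (4 rising and 5 falling of 17, adjusted p = 0.346 by limma camera), nor did the deep-layer markers (3 and 5 of 15, adjusted p = 0.109). Pou3f2, which is linked to upper-layer fate, rose from 512 ± 2.99 to 1060 ± 108 CPM (adjusted p = 0.000508). Tbr1 (adjusted p = 0.376) and Cux1 (adjusted p = 0.395) did not pass, and at the finer clustering the Cux1 slope passed on the rising side at 0.3 log2 per day. Clusters with a larger share of a layer list raised than of the newborn list carried layer names, so the naming itself limits these levels. Newborn neuron-like cells came from clusters 0 and 7 at E15 and from clusters 0 and 2 at E18. In all 1188 genes rose and 859 fell among 12025 tested. Without E15 replicate 1 the counts were 782 and 436, without E15 replicate 2 they were 812 and 463, and without E18 replicate 2 they were 767 and 546. With the stricter cell filter 231 rose and 200 fell, at the finer clustering, where E13 held enough such cells for all 10 libraries to be used, 2287 rose and 2257 fell, and with E16 and E18 replicates 1 left out 1507 fell.

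Of 31 lists tested in newborn neuron-like cells 12 passed, none with an estimated correlation. All 12 interneuron markers rose (12 adjusted over the list alone, adjusted p = 1.17e-10, adjusted p = 0.102 with an estimated correlation), from a summed 10.1 ± 2.47 CPM at E15 to 76.8 ± 9.34 at E18. Neurogenic differentiation genes fell for 7 of 18 (10 adjusted over the list alone, adjusted p = 4.84e-05, adjusted p = 0.309 with an estimated correlation), with Neurod6 from 1510 ± 12.9 to 758 ± 45.7 CPM. Astroglial transcripts in the newborn sums rose for 10 of 24 genes with 2 falling (12 and 2 adjusted over the list alone, adjusted p = 0.000215, adjusted p = 0.102 with an estimated correlation), with Sparcl1 at 29.5 ± 1.27 CPM and Slc1a3 at 53.7 ± 4.98 CPM at E18. Astrocyte markers summed to 61.4 ± 1.4 CPM there and to 1150 ± 124 CPM in NSC-like cells at E18. Free RNA was not removed and its part in the astroglial rise was not tested, so that rise is not assigned to the newborn neuron-like cells themselves. Notch pathway genes fell for 8 of 17 with 2 rising (10 and 2 adjusted over the list alone, adjusted p = 0.0026, adjusted p = 0.102 with an estimated correlation), among them Hey1 (38.7 ± 4.37 to 5.17 ± 0.475 CPM). Early progenitor genes fell for 6 of 11 with 1 rising (6 and 1 adjusted over the list alone, adjusted p = 0.00254). FGF and ERK targets rose for 7 of 12 with 2 falling (9 and 2 adjusted over the list alone, adjusted p = 0.00385). With an estimated correlation both had adjusted p = 0.309. Upper-layer identity genes rose for 5 of 20 with 1 falling (7 and 2 adjusted over the list alone, adjusted p = 0.0101, adjusted p = 0.534 with an estimated correlation). The remaining lists that passed were outer radial glia, ribosomal proteins, and the astrocyte, IPC and upper-layer markers (adjusted p from 0.0026 to 0.028, and from 0.309 to 0.736 with an estimated correlation). The median, mean and test differed in sign for the deep-layer identity and glycolysis lists and for the NSC and deep-layer markers.

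IPC-like and NSC-like cells of the same libraries were set against each other to ask which genes age differently in them. Zfhx4 fell in NSC-like cells (log2 -1.08 over 5 days) and rose in IPC-like cells (log2 1.39), a difference of 2.47 ± 0.12 (SE, adjusted p = 1.44e-08). Pkdcc likewise fell by 1.58 in NSC-like cells and rose by 2.15 in IPC-like cells. The homeobox gene Meis2 rose in IPC-like cells alone (log2 1.03), the LIM-domain gene Lmo3 rose there (log2 1.97) and fell slightly in NSC-like cells (log2 -0.44), and Mpped2 fell in NSC-like cells (log2 -1.28). In the other direction Plpp3, a lipid phosphatase gene, rose by 0.94 in NSC-like cells and fell by 1.47 in IPC-like cells (difference -2.38 ± 0.12, adjusted p = 1.44e-08), and Igfbp2, Mfsd2a and Fjx1 also rose in NSC-like cells and fell in IPC-like cells. Dtna rose in both, by 5.23 and 1.33. Pax6 and Sox2 differed in slope, by 0.9 ± 0.12 and 0.89 ± 0.12 over 5 days toward IPC-like cells (adjusted p = 3.55e-05 and 5.46e-05). Of the other regulators named in advance, Dnmt1 (adjusted p = 0.000768), Neurog2 (0.00123), Ctcf (0.00142), Dnmt3b (0.00963) and Ezh2 (0.0313) also had a more positive slope in IPC-like cells, and Eomes (0.00264) a more negative one. Hmga2, Hes1, Hes5, Dnmt3a and Tet1 did not differ past the threshold (adjusted p from 0.351 to 0.701). Among 13099 genes tested, 1802 had a more positive and 1904 a more negative slope in IPC-like cells. The first count was 1165 without E13 replicate 1. Of 11543 genes in all 3 fits, 1315 rose in both classes and 1260 fell in both, while 74 rose in NSC-like and fell in IPC-like cells and 22 did the reverse.

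Shares of cells per class were followed over age. NSC-like cells made up 36.1% ± 7.95 of kept cells at E13 (SD, n = 2), 17.1% ± 1.58 at E15 and 12.5% ± 3.24 at E18, with r = -0.852 against age (permutation p = 0.00111, adjusted p = 0.00259) and rho = -0.837 (permutation p = 0.00466). Without both E13 libraries r was -0.62. IPC-like cells went from 25.1% ± 2.54 to 9.15% ± 2.91 (r = -0.908, permutation p = 0.00032, adjusted p = 0.00112; rho = -0.911, permutation p = 0.00083; r = -0.728 without E13). Interneuron-like cells rose from 0.852% ± 0.0761 to 9.65% ± 0.282 (r = 0.928, permutation p = 0.00024, adjusted p = 0.00112; rho = 0.935, permutation p = 0.00037; r = 0.808 without E13). Excitatory neurons of all clusters, with cluster 4 counted among them, went from 31.4% ± 6.66 at E13 to 60.8% ± 0.828 at E15 and 57.2% ± 8.12 at E18 (r = 0.714, permutation p = 0.0201, adjusted p = 0.0282; rho = 0.542, permutation p = 0.118). At E13 nearly all were cells of cluster 4 (31.2% ± 6.53), which stayed unnamed, with IPC as its best type and deep-layer genes among its top genes. The finer clustering held a newborn neuron-like cluster with 1029 and 647 E13 cells and a deep-layer neuron-like cluster with 761 and 645. The excitatory neuron relation rested on the E13 libraries, since r was -0.24 without both, and it did not pass at 0.607 or 0.553 without E13 replicate 1 or 2. Microglia-like (r = 0.622, permutation p = 0.0352, adjusted p = 0.0411; rho = 0.763, permutation p = 0.0154; r = 0.646 without E13) and endothelial-like cells (r = 0.738, permutation p = 0.012, adjusted p = 0.021; rho = 0.862, permutation p = 0.00304; r = 0.776 without E13) stayed at or below 1.47% of any library. The cluster named endothelial-like also had all 8 mural markers raised, with Rgs5 and Vtn among its top genes, and the finer clustering gave 88 endothelial-like and 65 mural-like cells. The microglia-like relation did not pass at 0.617, 0.61, 0.614 and 0.614 without E13 replicate 1, E13 replicate 2, E15 replicate 1 or E15 replicate 2, and the endothelial-like relation not at 0.693 without E13 replicate 2. Without both libraries of highest mitochondrial share the microglia-like relation did not pass either. Cajal-Retzius-like cells showed no relation (r = 0.00103, permutation p = 0.998; rho = 0.0492, permutation p = 0.919; r = 0.356 without E13). These 7 classes formed 1 family.

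The 3 excitatory neuron classes with few E13 cells at resolution 1 and the unnamed cluster 19 were followed over 8 libraries as a family of 4. Deep-layer neuron-like cells went from 19.2% ± 1.6 at E15 to 3.48% ± 2.84 at E18 (r = -0.915, exact permutation p = 0.00556, adjusted p = 0.0106; rho = -0.83, exact permutation p = 0.0198). Newborn neuron-like cells went from 22.7% ± 0.855 to 34.8% ± 3.53 (r = 0.861, exact permutation p = 0.00794, adjusted p = 0.0106; rho = 0.781, exact permutation p = 0.0349). Upper-layer neuron-like cells did not pass (r = 0.237, exact permutation p = 0.555; rho = 0.293, exact permutation p = 0.513), but r was 0.614 without E18 replicate 1, not past the threshold, and 0.791, past it, with up to 20% mitochondrial UMIs allowed. Cluster 19, which carried Olig1, Olig2 and Pdgfra beside stem cell genes and stayed unnamed, rose from 0.112% ± 0.078 at E15 to 7.67% ± 0.766 at E18 (r = 0.9, exact permutation p = 0.000794, adjusted p = 0.00317; rho = 0.976, exact permutation p = 0.000794). At the finer clustering the relations of newborn neuron-like cells and of all excitatory neurons did not pass. Shares also depended on the cell filter: with at least 1500 genes and at most 5% mitochondrial UMIs, r became -0.359 for NSC-like and -0.612 for IPC-like cells, 0.0243 for excitatory neurons, 0.0976 for endothelial-like and -0.428 for newborn neuron-like cells, none past the threshold. Median mitochondrial share was 14.6% in E18 replicate 1 and 8.58% in E16 replicate 1, and from 5.14% to 7.62% in the other 8 libraries.

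**Figure D3:**
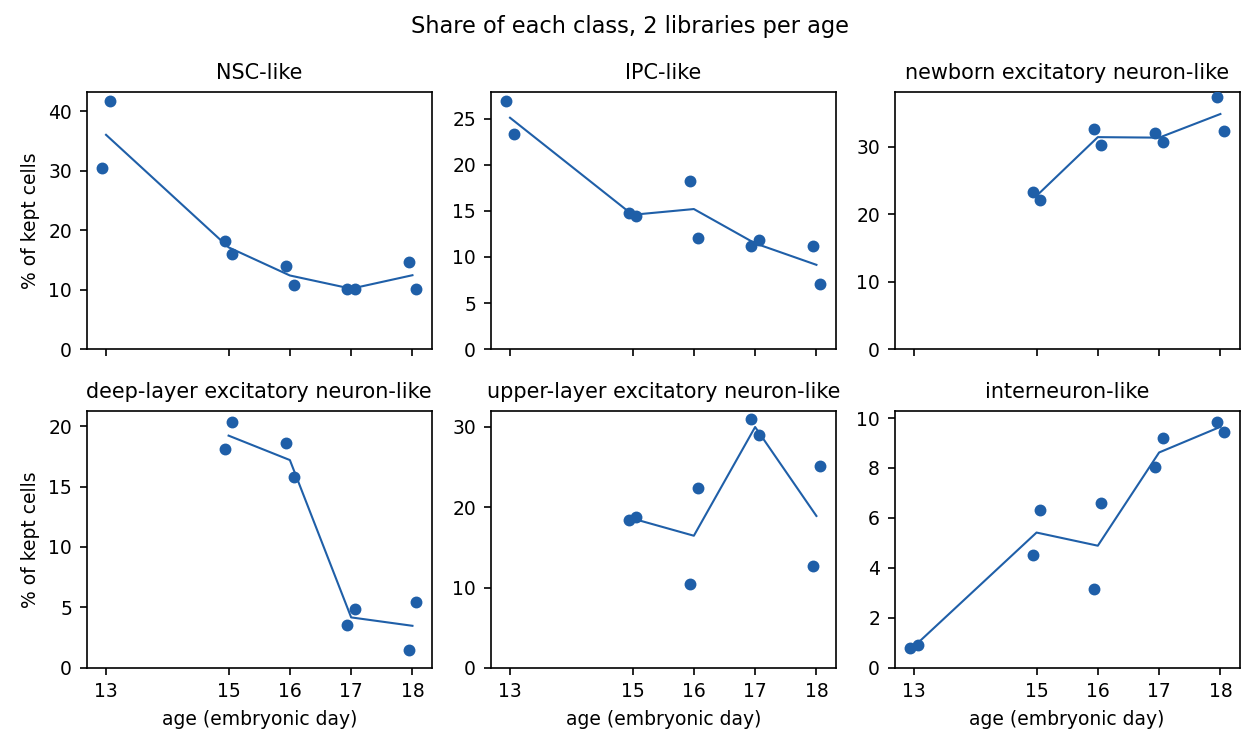
Share of kept cells in 6 classes against age in embryonic days; each point is 1 of 2 libraries per age and each line joins the means. Excitatory neuron classes are drawn from E15 on, and NSC-like cells go from 36.1% at E13 to 12.5% at E18.

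Cell cycle phase calls within classes were compared at a fixed depth of 2000 UMIs per cell. The share of NSC-like cells called S or G2/M was 84.7% ± 2.5 at E13 (SD, n = 2), 75.8% ± 1.54 at E15, 68.5% ± 7.19 at E16, 55.6% ± 0.675 at E17 and 34% ± 0.144 at E18. Against age r was -0.929 (permutation p = 0.00032) and rho -0.985 (permutation p = 2e-05), with r = -0.961 without both E13 libraries. Cells under 2000 UMIs left out were 13, 2, 0, 4 and 5 in age order, and unthinned shares were 85% at E13 and 34.9% at E18. In IPC-like cells the share went from 49.1% ± 11.6 at E13 to 37% ± 7.26 at E18 without a relation to age (r = -0.204, permutation p = 0.57; rho = 0.0492, permutation p = 0.919; r = 0.553 without E13). The IPC-like values depended on the clustering, by unthinned phase calls scored over all kept cells. In the main classes 44.4% and 61.9% were called S or G2/M at E13 and 44.7% and 34.1% at E18. At Leiden resolution 2 these were 57.6% and 80.5% at E13 and 33.6% and 33.1% at E18, and a relation to age was not tested there. Phase calls rest on scores of the S and G2/M lists tested above, so the falls of lists and shares are not separate results. They do not by themselves measure division, and free RNA was not removed.

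**Figure D4:**
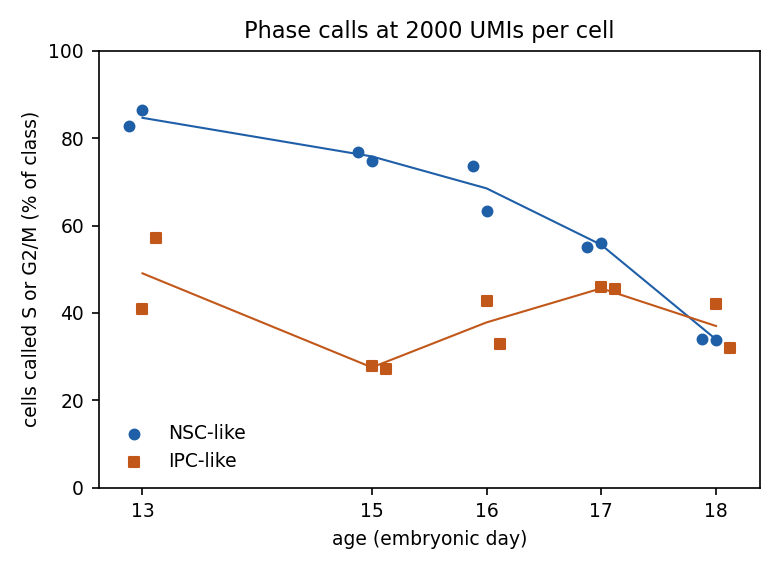
Share of NSC-like cells (circles) and IPC-like cells (squares) called S or G2/M, in percent of the class at 2000 UMIs per cell, against age in embryonic days. Each point is 1 of 2 libraries per age and each line joins the means; NSC-like cells go from 84.7% at E13 to 34% at E18.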

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

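The 2 tests of the phase share below, and the ratios of the second highest interneuron marker, were chosen only after the results had been seen; the other tests of this part were written before their results.

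Genes that age differently in IPC-like and NSC-like cells stood out as a difference between groups, tested by the interaction of class and age: 1802 genes had a more positive and 1904 a more negative slope in IPC-like cells, with 1165 of the first kind without E13 replicate 1. Cluster 4, with 2631 cells, is a signal in data outside the gene comparisons, and its top genes included Slc17a7, Bcl11b, Tbr1 and Sox5. Cluster 19, with 737 cells led by Olig1, Olig2, Pdgfra and Egfr, is likewise outside the gene comparisons. So are cluster 20, with 450 cells of low depth whose top genes were of haemoglobin, and cluster 23, with 230 cells, 79.6% of them from E13 replicate 2.

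The first pattern weighed is the change of many genes in NSC-like cells with age. A batch that set the E13 libraries apart is argued against as the whole cause by the signs of slopes within the E16 to E18 libraries. Of the genes called between E13 and E15, 77.6% kept their sign there (641 of the 826 also tested, interval 74.6 to 80.3). The E13 to E15 contrast did not compare the levels of the E16 to E18 libraries, though they entered its dispersion. The share was 84.2% for rising and 64.6% for falling genes. The interval treats genes as independent, which genes of the same libraries are not, so it may be too narrow. The share of rising slopes among all genes there is not given. These signs cannot exclude that a batch set part of the E13 to E15 calls. A smaller share of cells called S or G2/M in the sums is argued against as the whole cause. Slopes in cells called G1 were a median of 1.04 times those in all cells over 4850 genes (quartiles 0.775 and 1.3), 98.2% with the same sign. A G1 call is a low score for S and G2/M genes, so cells that left the cycle carry it too. The G1 fit therefore cannot speak to a growing part of such cells. Among 100 orders of the ages, the real one included, 1 gave as many called genes, the real one with 6154, and the highest other gave 2996. These values are consistent with a change of the cells with age, as a hypothesis found and tested on the same data, and a growing astrocyte-like subset among NSC-like cells, and differences between litters or dissections of each age, stay open, as the first was not tested and the labels name no litter or day.

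The second pattern is the rise of most interneuron marker genes in NSC-like, IPC-like and newborn neuron-like cells. Their summed level in NSC-like cells did not rise, with 245 ± 24.2 CPM at E13 and 179 ± 25.6 at E18. RNA of interneurons, free or in doublets, would set the marker genes at 1 common fraction of their interneuron-like level, and the ratio of the highest to the lowest fraction in the 2 libraries of E18 was 49.3 and 23.8 in NSC-like, 17.1 and 13.5 in IPC-like and 4.97 and 10 in newborn neuron-like cells. The first 2 classes exceed the bound of 10 set in advance against this source, but that bound was wrong in letting a single gene decide for a list, since the second highest gene gave ratios of 6.69 and 7.4 in NSC-like and 6.95 and 6.14 in IPC-like cells. With these and the 4.97 between the bounds, this source cannot be told apart from expression in the cells themselves for the rise of the list. Interneuron-like cells went from 0.852% to 9.65% of kept cells between E13 and E18, so more free RNA may be present at later ages, and no biological explanation was tested.

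The third pattern is the fall of the share of NSC-like cells called S or G2/M. Lower depth at later ages is argued against, since r was -0.929 with each cell thinned to 2000 UMIs. The naming of clusters is argued against as the whole cause, since r was -0.896 in cells taken by Pax6 without Eomes, Neurod2 or Neurod6. The share went from 84% to 46.9% in these cells and from 84.7% to 34% in the named class. By phase calls scored over all kept cells, joining the Olig1 and Olig2 cluster moved the E18 shares from 41.3% and 41.4% to 51.7% and 53.9%. Naming may thus set part of the size of the fall. A lengthening or leaving of the cell cycle with age is a possible explanation consistent with the r of -0.896 and -0.929 but was not tested, since phase calls do not measure division.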

How the results depend on the processing

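The looser mitochondrial limit, the E15 to E18 trends, the fits without both libraries of highest mitochondrial share and the joined Olig1 and Olig2 cluster were chosen after the data were seen, and the other settings before. Over all settings and single libraries left out, 6782 gene values kept direction and side of the threshold, 236 lost and 99 gained the threshold, and 7 reversed, where a reversal needs the threshold passed in at least 1 of the fits. For lists the numbers were 283, 49, 24 and 3. Size factors of DESeq2 in edgeR left all 336 gene values in place. Joining astrocyte-like clusters was not run, as neither resolution gave a cluster of that name. Fewer UMIs at E17 and E18 limit genes of low level, and leaving out a library leaves a lone sample that is assumed to vary like the other ages. Except where noted, the cause was not tested.

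Counts of NSC-like genes between neighbouring ages (882, 140, 128 and 615) moved most. They were 1384, 610, 527 and 1230 with no filter on low counts, where more genes are tested; DESeq2 gave 228 and 249 for E15 to E16 and E16 to E17. Thinned sums gave 447 and 81 for the first 2 steps; G1 cells gave 100, 17 and, at the last step, 240; the Pax6 gate gave 505, 15, 24 and 4. Without both libraries of highest mitochondrial share the last 3 steps gave 31, 67 and 198, and the joined Olig1 and Olig2 cluster gave 109 at the last. With each library left out in turn they ranged from 304 to 1007, 5 to 329, 30 to 234 and, by edgeR, 0 to 919, with 1661 genes at an unadjusted p under 0.05 where the count was 0 and 666 by DESeq2 on all libraries. The NSC-like trend had 1878 rising and 1478 falling genes in G1 cells and 1863 falling with the Pax6 gate; E18 against E13 had 1876 and 1506, and 2165 and 1661. These sets hold fewer cells.

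The IPC-like trend had 872 rising and 566 falling genes from E15 to E18, with fewer libraries, and 1257 rising with the stricter cell filter. The newborn trend had 231 and 200 with that filter, 2287 and 2257 at Leiden resolution 2, 1507 falling without both libraries of highest mitochondrial share, and from 767 to 1355 rising and 436 to 1086 falling with each library left out. Genes with a more positive slope in IPC-like cells ranged from 1165 to 1810. With estimated correlation camera called 3 NSC-like lists, 0 IPC-like and 0 newborn lists, while fry called 22, 21 and 13.

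Reversed slopes in log2 per day were, from E15 to E18, NSC-like Hes5 -0.22; in G1 cells, NSC-like Rpa2 0.0804 and IPC-like Mki67 -0.079; with the stricter filter, IPC-like G2e3 0.0026 and Eomes -0.0902; at resolution 2, newborn Id4 -0.14 and Etv1 -0.102. Rpa2 and Mki67 are members of the lists that set the G1 calls. IPC-like lists turned from E15 to E18 for cholesterol synthesis (adjusted p = 0.859, limma camera), immediate early genes (0.0185) and ribosomal proteins (0.000624).

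Shares related to age less with the stricter filter (r = -0.359 for NSC-like, -0.612 for IPC-like, 0.0243 for all excitatory neurons, 0.0976 for endothelial-like cells), and newborn neurons turned to -0.428, none of them past the threshold. At resolution 2 all excitatory neurons gave 0.625 and newborn neurons 0.7, neither past the threshold. Microglia-like cells gave 0.712, not past the threshold, without both libraries of highest mitochondrial share, and upper-layer neurons passed at 0.791 with the 20% limit. With each library left out r ranged from 0.553 to 0.848 for excitatory neurons, 0.61 to 0.702 for microglia-like and 0.693 to 0.807 for endothelial-like cells.

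The labels do not say whether equal replicate numbers pair the samples, and they were not taken as pairs. A replicate block gave 333, 321 and 1116 genes at the last 3 steps of NSC-like cells, and ages permuted within replicates left microglia-like cells (r = 0.622) short of the threshold. With it the IPC-like oligodendrocyte lineage list had adjusted p = 0.0532 and the newborn cholesterol synthesis list 0.0457 (limma camera). The difference of replicate 1 minus replicate 2 in log2 CPM was correlated over genes between each pair of ages. These correlations ranged from -0.201 to 0.425 in NSC-like, -0.196 to 0.446 in IPC-like and -0.256 to 0.537 in newborn neuron-like cells. In the same order, 3, 3 and 1 pairs of ages were above 0.1 and 2, 2 and 2 below -0.1.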

Other observations

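Interneuron-like cells formed clusters of distinct make-up. Cluster 8, with 1374 cells, was led by Sst, Lhx6, Maf and Nxph1, genes typical of interneurons born in the medial ganglionic eminence. Cluster 18, with 828 cells, was led by Adarb2, Dlx6os1, Dlx1 and Nrxn3, and its top genes also held Htr3a and Prox1, typical of the caudal eminence. Cells of cluster 8 were present at E13 (34 and 35 cells per library) and numbered 141 and 203 at E15. Cells of cluster 18 numbered 0 and 2 at E13, 21 and 19 at E15, 111 and 183 at E17 and 130 and 307 at E18. These counts were not tested.

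Deep-layer neuron-like cells of cluster 3 (2912 cells, with Hs3st4, Sox5 and Tle4 among the top genes) numbered 649 and 715 at E15 and 13 and 110 at E18. Cluster 24 (181 cells, with S100a10, Tcerg1l and Ldb2) held 0 cells at E13 and E15 in each library and 14 and 101 at E18. Cluster 27, with Nts, Nr4a2 and Tshz2 among its top genes, had its 59 cells in E18 replicate 2 alone. In NSC-like cells the summed astrocyte markers went from 79.9 ± 8.08 CPM at E13 to 1150 ± 124 at E18 (SD, n = 2), and those of oligodendrocyte precursors from 1.69 ± 0.918 to 45.3 ± 0.863.

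Summed haemoglobin and other red blood cell markers in NSC-like cells were 402 ± 540 CPM at E13, 8.41 ± 1.83 at E15, 32.7 ± 19 at E16, 14.5 ± 1 at E17 and 812 ± 1090 at E18. In IPC-like cells they were 29.8 ± 8.63, 10.3 ± 2.31, 34.1 ± 15.7, 272 ± 302 and 39.6 ± 10.2 CPM. Between the 2 libraries of an age the chi-square per gene of the summed UMIs of all kept cells was 154 at E13, 9.66 at E15, 80.2 at E16, 12.3 at E17 and 75.8 at E18, and r of log2 CPM was 0.99, 0.998, 0.99, 0.996 and 0.982.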
